A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

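Total RNA of 18 cell culture samples (6 groups of 3) was extracted with TRIzol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The deposited files hold whole-number counts per gene in each sample, with no normalization, and these counts were used as the authors deposited them. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.7.3a and kallisto 0.46.2 and the builds GRCh38 and GRCm38. Which of these tools made the counts, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Without the strand setting, overlapping and antisense genes are uncertain, as are genes with near-identical copies.

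The human files hold 34505 gene identifiers, of which 34349 were named by a symbol table and 34474 are in GENCODE 29 (33619 with the same version). GENCODE 29 gave names and GRCh38 coordinates, and 31 identifiers had no name. The files hold 18929 of the 19951 protein-coding genes of that release, 15117 pseudogenes and 12 of 7629 lincRNA genes. None of the 34471 mouse identifiers was named by the tables used here, so mouse identifiers are printed as in the files, the row of mouse Krt17 was not determined, and mouse gene lists and the overlap of all 3 lines were not analysed here. Several abundant housekeeping genes had very low counts in the human files. TUBB had 0 counts in all 6 PANC-1 libraries, and EEF2 had 32 to 53 counts in L3.6 but 10960 to 27520 in PANC-1. CANX had 67 counts in PANC-1 empty vector replicate 2 and 16969 to 21772 in the other PANC-1 libraries. A row may therefore hold only part of a gene's reads, and the part may differ between lines or libraries. Levels may then not compare between genes or lines, and comparisons of the 2 human lines may rest on different parts of a gene.

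Depth per sample was taken as the sum of counts, from 9485257 to 70789559. Counting intervals are exact Clopper-Pearson intervals and floors are 3 counts, and both cover counting error only. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Samples were grouped by the treatment label of each sample.

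Each line was fitted alone with edgeR 4.0.16 (glmQLFit with robust spread, glmQLFTest, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. CPM values use TMM-scaled library sizes, and log CPM a prior count of 2. The difference of the K17 effects was tested as an interaction over the 12 human libraries in 1 edgeR fit. The overlap of calls was compared with the product of both call numbers over the genes tested and with Fisher's exact test, two-sided, over genes. Of 47 gene lists, without KRT17, those with at least 4 tested members (44 in L3.6, 46 in PANC-1) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. With an estimated correlation 0 lists passed in either line, with a lowest adjusted p of 0.385 in L3.6 and 0.0563 in PANC-1. Limma's fry, which tests whether a list moves on balance 1 way and does not compare it with other genes, called 11 lists in L3.6 and 22 in PANC-1.

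The grouping, the tests, the gene lists, the main alternatives and the rule for named genes were fixed before the data were examined. The rule names KRT17 and the keratins that pass. It then takes the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, leaving out clone and pseudogene names. It adds up to 4 members of each list described, or the 2 most abundant where none passes, and DHODH, CAD and UMPS. Lists described are those called by camera, those on tumour subtype, pyrimidines, gemcitabine and respiration, and markers of other cell types. In PANC-1 only 3 genes that fell met the rule. Some genes that the rule takes are not reported here.

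Alternatives were RLE and upper-quartile factors, no filter and a CPM filter, DESeq2 1.42.0, limma-voom, 1 fit of the 4 human groups, the replicate number as a block and each library left out in turn. Added after the data were seen were a correction for GC content and transcript length, quality weights per library, genes with 1 annotated transcript and a fit without the row AC010970.1.

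The scripts were tested on simulated data made from the real means, library sizes and fitted spread, with 100 genes changed 2-fold and 100 changed 4-fold. The spread of a gene was the same in all libraries of a line, so no simulated library stood apart as PANC-1 empty vector replicate 2 does. In the KPC design (14134 genes) 98 of the 2-fold and 100 of the 4-fold changes were found, with 28 of 226 calls wrong. In the L3.6 design (13757 genes) 76 and 97 were found, with 19 of 192 calls wrong. In the PANC-1 design (16129 genes) 1 and 78 were found, with 3 of 82 calls wrong, and without empty vector replicate 2 (16503 genes) 93 and 98, with 29 of 220 wrong. For the difference between lines (13263 genes) 11 and 76 were found, with 5 of 92 calls wrong. A shifted list was found in each of 3 simulated designs among 46 lists. In the design without PANC-1 empty vector replicate 2, 1 unshifted list was also called. Simulated genes varied independently of each other. In the real data the estimated correlation was 0.535 for ribosomal proteins in L3.6 and 0.973 for mitochondrial DNA genes in PANC-1. These simulations therefore do not cover false calls of lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.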

Results

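RNA was sequenced from 3 pancreatic cancer cell lines that differed in keratin 17 (K17, gene KRT17), an intermediate filament protein of stratified epithelium and a marker of basal-like pancreatic tumours. KPC is a mouse pancreatic ductal adenocarcinoma line, PANC-1 is a human line of the same tumour type and L3.6 is a human pancreatic adenosquamous carcinoma line. KPC and PANC-1 cells carried either an empty vector or K17, and L3.6 cells were either wild type or had KRT17 knocked out with CRISPR-Cas9. Each of the 6 groups had 3 libraries, 18 in all. The groups of a line may also differ in ways other than K17, such as clone or culture. The design cannot separate these from K17. The comparisons ask which transcripts differ with K17 in each line, in a study on mitochondrial K17 and resistance to chemotherapy. All fold changes below are K17-high minus K17-low, so in L3.6 they are wild type minus knockout.

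The libraries differed in depth between lines more than between groups of a line. KPC empty vector libraries held 30970804, 34489693 and 29141504 counts and KPC K17 libraries 24428154, 28161376 and 18270619. L3.6 knockout libraries held 12561589, 13800079 and 13093425 counts and wild-type libraries 15476629, 9485257 and 12081110. PANC-1 empty vector libraries held 70789559, 69750317 and 63280851 counts and PANC-1 K17 libraries 61507212, 59671178 and 60944758. PANC-1 empty vector replicate 2 stood apart from the other PANC-1 libraries. Genes of mitochondrial DNA took 18.8% of its counts, against 9.88% to 10.8% in the other 5, and its first principal component score was -135.1 against 22 to 31.6. In L3.6, wild-type replicate 1 scored 7.4 on the first component, between the knockout libraries (-40.6 to -18.6) and the other wild-type libraries (40.1 and 41.3). A pseudogene row, AC010970.1, took 4.34% to 6.96% of the knockout counts, 6.05% in wild-type replicate 1 and 13.5% and 14.1% in wild-type replicates 2 and 3. Replicate pairs all differed by more than sampling noise, with chi-square per degree of freedom of at least 3.5, so each library was counted as 1 sample.

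**Figure D1:**
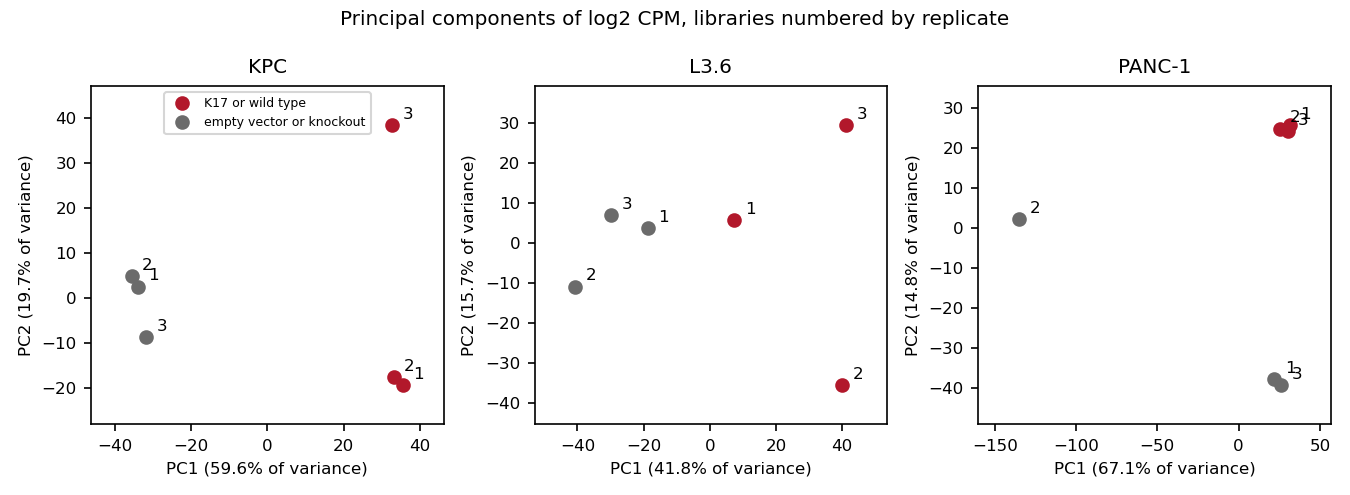
Principal components of log2 CPM in each cell line; each point is 1 library numbered by its replicate, red for K17 or wild type and grey for empty vector or knockout, and axes give the component scores with their percent of variance. PANC-1 empty vector replicate 2 lies at -135.1 on the first component, which holds 67.1% of the PANC-1 variance, and L3.6 wild-type replicate 1 lies at 7.4 between the remaining libraries of its line.

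KRT17 followed the labels in both human lines. In L3.6, KRT17 was counted 202, 204 and 175 times in the knockout libraries and 1654, 1112 and 1420 times in the wild type, or 14.6 ± 1.03 against 115 ± 8.66 CPM (SD, n = 3 each). The log2 fold change was 2.98 with a standard error of 0.088 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.29e-06), so the knockout libraries still held KRT17 reads at a 7.79-fold lower level. In PANC-1 with the empty vector, KRT17 had 2, 0 and 0 counts, where 3 counts would equal 0.0426 to 0.0502 CPM. The K17 libraries had 8597, 9884 and 9228 counts, or 151 ± 13.1 CPM (SD, n = 3), a ratio of 15300 with a 95% counting interval of 4230 to 126000 (exact Clopper-Pearson). The fitted log2 fold change of 13.65 depends on the prior count (edgeR adjusted p = 0.00646). It was 13.13 without PANC-1 empty vector replicate 2 (edgeR adjusted p = 7.36e-06), while leaving out empty vector replicate 3 or any single K17 library gave edgeR adjusted p values of 0.0773 to 0.127. The row is ENSG00000128422.15 (chromosome 17, 41619441 to 41624842, GRCh38), a gene-level count that does not separate an introduced from an endogenous copy, and the near-identical pseudogene KRT17P2 had 17, 15 and 23 counts in the PANC-1 K17 libraries and 0 in the empty vector libraries. Which mouse row is Krt17 was not determined, because the tables used here pair no mouse identifier with a gene name.

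**Figure D2:**
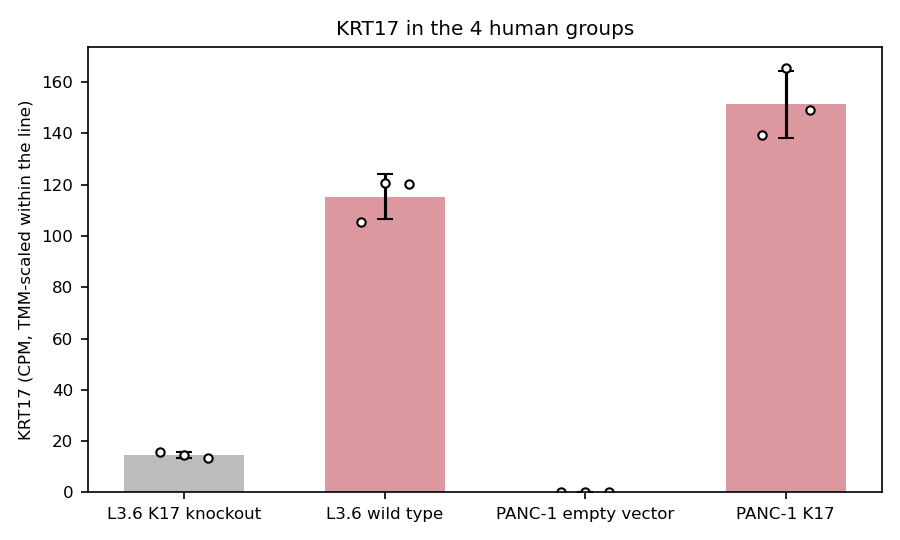
KRT17 in CPM (TMM-scaled within each line) in the 4 human groups; bars are means, error bars are SDs of 3 libraries and points are libraries. Wild-type L3.6 averaged 115 CPM against 14.6 in the knockout, and PANC-1 K17 averaged 151 CPM against an empty vector group with 2, 0 and 0 counts.

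In KPC cells the K17 and empty vector libraries differed in a large part of the transcriptome. Of 14257 genes tested, 4990 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 2660 higher and 2330 lower with K17, and 633 of them changed by at least 2-fold (426 up, 207 down). More genes were lower than higher with RLE factors (2385 higher, 2518 lower), no filter (2115 and 3324), the CPM filter (2416 and 2466), DESeq2 (1884 and 2104) and without K17 replicate 3 (2695 and 2916). The row ENSMUSG00000035557 stood at 69.3 ± 1.97 CPM (SD, n = 3) with K17 and had 0 counts in all 3 empty vector libraries, at least 2210-fold higher against a floor of 3 counts over the group. The row ENSMUSG00000045545 stood at 37.3 ± 1.28 CPM with K17 and at 0 with the empty vector, at least 1190-fold higher by the same floor. Whether these 2 rows hold reads of the introduced K17 was not determined, so they may not be separate changes of the cells' own transcripts. The row ENSMUSG00000022829 stood at 47.8 ± 1.75 CPM with the empty vector and had 1 count in the 3 K17 libraries together, a ratio of 3360 with a 95% counting interval of 603 to 133000. The row ENSMUSG00000070436 fell from 88.7 ± 1.87 to 1.18 ± 0.129 CPM, a log2 fold change of -6.24 with a standard error of 0.078 (edgeR adjusted p = 1.25e-17). KPC K17 replicate 3 scored 38.4 on the second component, against -19.4 and -17.6 for the other K17 libraries. Gene lists were not tested in KPC, since no symbols were at hand.

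In L3.6, wild-type cells had more transcript of the chemokines CXCL1 and CXCL3 and of complement component C3, and less of EFEMP1 and the YAP target ANKRD1, than K17 knockout cells. CXCL1, a neutrophil-attracting chemokine, stood at 16.4 ± 2.01 CPM in the wild type and 2.06 ± 0.245 CPM in the knockout (SD, n = 3 each), a log2 fold change of 2.98 with a standard error of 0.192 (edgeR adjusted p = 9.06e-05). CXCL3, a related chemokine, rose by 2.54, TNFAIP2, a gene induced by tumour necrosis factor, by 2.80 to 122 CPM, and complement component C3 by 2.00 from 36.1 ± 2.57 to 145 ± 12.2 CPM. ANKRD1, which encodes an ankyrin repeat protein of muscle, stood at 0.813 ± 0.289 CPM in the wild type and 28.8 ± 3.7 CPM in the knockout, a log2 fold change of -5.20 with a standard error of 0.246 (edgeR adjusted p = 2.33e-05). EFEMP1, an extracellular matrix glycoprotein, had a log2 fold change of -3.06, at 59.5 ± 8.15 against 496 ± 14.6 CPM (edgeR adjusted p = 3.29e-06). Of the 23 tested genes of the extracellular matrix list, which EFEMP1 is not part of, 5 fell and 2 rose, 6 and 4 when adjusted over the list alone (camera adjusted p = 0.889).

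The other genes with the largest L3.6 changes included further secreted and receptor genes. Among those that rose, HEATR4 changed by 3.86 on the log2 scale, IGFBP3, a carrier of insulin-like growth factors, by 2.48, the adhesion receptor ADGRF1 by 2.44, the interleukin 18 receptor subunit IL18RAP by 1.98, the glucuronosyltransferase UGT1A4 by 1.79 and osteopontin, SPP1, by 1.78. UGT1A4 shares its last exons with the other UGT1A genes, so its reads can be split between them. Among those that fell, the growth factor PDGFB changed by -4.06, the neurotrophin BDNF by -2.88, the matrix metalloprotease MMP2 by -2.72, the kinase CAMK2B by -2.70, the kinase DCLK1 by -2.52, PLXDC2 by -2.14 and the chemokine receptor CXCR4 by -2.11. All of these passed edgeR's test in 3 against 3 libraries, with adjusted p values up to 0.0201 (UGT1A4). CXCL1 is on chromosome 4 (73869393 to 73871242), ANKRD1 on chromosome 10 (90912096 to 90921276), EFEMP1 on chromosome 2 (55865967 to 55924139) and C3 on chromosome 19 (6677704 to 6730562), all in GRCh38.

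In all, 1335 of 13891 genes passed edgeR's test in L3.6, 488 higher and 847 lower in the wild type, and 245 changed by at least 2-fold (119 up, 126 down). With upper-quartile scaling the split was 639 higher and 706 lower. Leaving out wild-type replicate 1 gave 2493 genes, and leaving out each of the other libraries gave 574 (knockout replicate 2), 576 (knockout replicate 3), 659 (wild-type replicate 2), 786 (wild-type replicate 3) and 807 (knockout replicate 1).

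Among keratins of L3.6 other than KRT17, KRT7 and KRT19, keratins of simple epithelium, fell in the wild type by 0.52 and 0.30 on the log2 scale (edgeR adjusted p = 0.0326 and 0.0212). None of the 4 tested stratified keratins passed, and KRT13 and KRT10 had log2 fold changes of 0.36 and 0.11.

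Camera called several gene lists written before the data were examined in L3.6 at its preset correlation, and 0 with an estimated correlation. Of the 9 tested NF-kB targets and chemokines, 4 rose and none fell, 7 when adjusted over the list alone, led by CXCL1 and CXCL3. PTGS2, the inducible cyclooxygenase, rose by 1.36 and NFKBIA, the NF-kB inhibitor, by 0.81. Limma's camera called the list up (adjusted p = 9.31e-05), but not with an estimated correlation (adjusted p = 0.385 with an estimated correlation). Of 13 tested YAP targets, 4 fell and none rose, 6 when adjusted over the list alone. Beside ANKRD1 these were the angiomotin-like genes AMOTL1 (-1.81) and AMOTL2 (-0.63) and the receptor kinase AXL (-1.01). The YAP list was called down (camera adjusted p = 0.000746, adjusted p = 0.549 with an estimated correlation). Of 15 mesenchymal genes 4 fell and none rose, 6 when adjusted over the list alone. They were MMP2, AXL, the lysyl oxidase LOXL2 (-0.76) and vimentin, VIM (-0.62), with the list called down (camera adjusted p = 0.0125, adjusted p = 0.41 with an estimated correlation).

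Lists of cell adhesion, division, sterol synthesis and ribosomal proteins were also called down by camera in L3.6, at the preset correlation only. Of 15 integrin and hemidesmosome genes 6 fell and 1 rose, the same numbers when adjusted over the list alone. The integrin subunits ITGB6 and ITGB8 had log2 fold changes of -1.78 and -1.07, the linker DST of -0.44 and ITGA3 of 0.26 (camera down, adjusted p = 0.0125, adjusted p = 0.41 with an estimated correlation). Of 27 mitosis genes 5 fell and none rose, 10 when adjusted over the list alone, among them the kinase AURKB (-0.80), the phosphatase CDC25C (-0.61), CDK1 (-0.37) and BUB1B (-0.22; camera adjusted p = 0.00769, adjusted p = 0.752 with an estimated correlation). Of 20 genes of cholesterol synthesis and uptake 4 fell and none rose, 8 when adjusted over the list alone. Among them, HMGCS1 changed by -0.40, DHCR7 by -0.38 and FDPS by -0.25 (camera down, adjusted p = 0.015, adjusted p = 0.481 with an estimated correlation). Of 30 ribosomal protein genes 4 fell and 1 rose, and 12 fell and 2 rose when adjusted over the list alone. RPS15 (-0.33), RPL13 (-0.31) and RPS2 (-0.28) fell and RPL27 (0.33) rose (camera down, adjusted p = 0.0125, adjusted p = 0.963 with an estimated correlation).

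Camera called none of the 5 lists on tumour subtype, pyrimidines and gemcitabine in L3.6, while limma's fry called the basal-like and the salvage and breakdown lists down (adjusted p = 0.0028 and 0.00853). Of 11 tested genes of the basal-like pancreatic cancer signature, 5 fell and 1 rose in the wild type, the same numbers when adjusted over the list alone. The growth factor binding protein FGFBP1 changed by -0.83, S100A2 by -0.46 and the adhesion protein TNS4 by 0.90 (camera adjusted p = 0.215). Of 5 classical signature genes 1 fell, ANXA10 by 0.54, 1 when adjusted over the list alone (camera adjusted p = 0.889). Of 16 genes of pyrimidine synthesis 1 fell, the nucleotide kinase CMPK2 (-1.30), and 1 when adjusted over the list alone (camera adjusted p = 0.879). DHODH, the mitochondrial enzyme of this pathway, had a log2 fold change of -0.47 ± 0.181 (SE; edgeR adjusted p = 0.143). CAD, its first enzyme, had -0.77 ± 0.463 (SE) and UMPS, its last, -0.04 ± 0.076 (SE), neither passing edgeR's test. Of 17 genes of pyrimidine salvage and breakdown 4 fell and none rose, 4 when adjusted over the list alone. They were the nucleotidase NT5E (-1.06), the deaminase DCTD (-0.46), DPYD (-0.43), which starts pyrimidine breakdown, and the mitochondrial kinase TK2 (-0.40; camera adjusted p = 0.215). DCTD and TK2 were also the 2 called among 19 genes of gemcitabine handling, where 5 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.764).

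Few transcripts of the respiratory chain passed edgeR's test in L3.6. Of 13 protein genes of mitochondrial DNA, MT-ND1 rose by 0.26 while MT-ND4 (-0.23) and MT-ND4L (-0.24) fell, with the same numbers when adjusted over the list alone (camera adjusted p = 0.938). The list's median was 0.00 and its mean -0.01. Of 33 nuclear genes of complex I and 22 of complexes II to IV, none passed edgeR's test or when adjusted over the list alone (camera adjusted p = 0.938 and 0.948). Their most abundant members changed by 0.14 (NDUFB5), -0.19 (NDUFV1), 0.15 (CYCS, cytochrome c) and -0.08 (SDHA) on the log2 scale. Of 15 ATP synthase genes 1 rose, ATP5MC1 by 0.34, and 1 when adjusted over the list alone (camera adjusted p = 0.938), with a median of -0.02 and a mean of 0.06. Among markers of other cell types, 4 endothelial genes were tested and 1 rose, the adhesion molecule PECAM1 by 1.40 at a mean of 6.71 CPM, 2 when adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.421 with an estimated correlation). Of 6 fibroblast markers 1 rose, the collagen gene COL1A1 by 0.41, and 1 fell, PDPN (-0.84), with the same numbers when adjusted over the list alone (camera adjusted p = 0.889). Only 3 immune and 2 acinar or islet markers had enough counts to be tested singly, and none passed edgeR's test or when adjusted over the list alone.

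In PANC-1, cells with K17 had more transcript of the collagen genes COL13A1 and COL1A1, of WNT5A and of sterol genes than cells with the empty vector. COL13A1, a transmembrane collagen, rose from 1.93 ± 0.69 to 14.7 ± 0.754 CPM (SD, n = 3 each), a log2 fold change of 2.93 with a standard error of 0.285 (edgeR adjusted p = 0.025). WNT5A, a secreted Wnt ligand, rose by 2.68 to 15.8 ± 0.579 CPM and COL1A1, a chain of type I collagen, by 2.31 from 28.1 ± 10.5 to 140 ± 3.08 CPM. INSIG1, a sterol-regulated protein of the endoplasmic reticulum, rose by 2.12 from 16.3 ± 3.31 to 70.7 ± 5.17 CPM (edgeR adjusted p = 0.0221). The receptor kinase ERBB2 changed by -1.19 from 25.7 ± 3.95 to 11.2 ± 0.756 CPM and the serine protease TMPRSS2 by -1.59 (edgeR adjusted p = 0.0489 and 0.0307).

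The other named PANC-1 genes that rose were the adenylate kinase AK5 (2.26), the kinase MAST4 (2.09), the hyaluronan receptor LAYN (2.03), TMEM255B (2.02), MANSC1 (1.93) and the fatty acid receptor FFAR4 (1.81), all log2 fold changes past edgeR's test. The third gene that fell under the naming rule was EFHD1, which encodes a mitochondrial calcium-binding protein, from 12.3 ± 3.37 to 3.08 ± 0.6 CPM. COL13A1 is on chromosome 10 (69801867 to 69964275), WNT5A on chromosome 3 (55465715 to 55490539), INSIG1 on chromosome 7 (155297776 to 155310235) and ERBB2 on chromosome 17 (39687914 to 39730426), all in GRCh38.

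In all, 105 of 16295 genes passed edgeR's test in PANC-1, 95 higher and 10 lower with K17, and 100 changed by at least 2-fold (90 up, 10 down). Without PANC-1 empty vector replicate 2, 3442 of 16640 genes passed, 1902 higher and 1540 lower, and 494 changed by at least 2-fold (389 up, 105 down). All 105 genes were among the 3442 with the same direction. Leaving out empty vector replicate 1 gave 1 gene, and leaving out empty vector replicate 3 or K17 replicate 1, 2 or 3 gave 0 by edgeR, with 1713, 979, 1010 and 1028 genes at an unadjusted p under 0.05. DESeq2 called 511 genes and limma-voom 141 in all 6 libraries. None of the keratins other than KRT17 passed in PANC-1, where KRT80 had a log2 fold change of 1.48 ± 0.287 (SE; edgeR adjusted p = 0.11). Without empty vector replicate 2, KRT80 rose by 1.81 and KRT8 by 0.16 (edgeR adjusted p = 0.000542 and 0.00978).

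Several genes of cholesterol synthesis and uptake rose in PANC-1, and most of those tested did without empty vector replicate 2. Of 19 tested, 5 rose and none fell, 11 when adjusted over the list alone. Beside INSIG1 they included DHCR7, which makes cholesterol in the last step (1.60), and IDI1 (1.21). Camera called the list up (adjusted p = 2.66e-12, adjusted p = 0.0563 with an estimated correlation). Without empty vector replicate 2, 17 of 19 rose and none fell, 18 when adjusted over the list alone (camera adjusted p = 4.59e-13, adjusted p = 0.357 with an estimated correlation). Of 17 genes of fatty acid metabolism 1 rose, the desaturase FADS2 by 1.35, 3 when adjusted over the list alone (camera adjusted p = 0.0329, adjusted p = 0.316 with an estimated correlation). Without that library 8 rose and 1 fell (camera adjusted p = 0.046, adjusted p = 0.357 with an estimated correlation).

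Of 23 interferon-stimulated genes none passed edgeR's test over all genes with all 6 libraries, and 10 rose when adjusted over the list alone. MX2, an antiviral GTPase, had a log2 fold change of 0.17 ± 0.2 (SE), and camera called the list up (adjusted p = 5.31e-08, adjusted p = 0.0654 with an estimated correlation). Without empty vector replicate 2, 13 of the 23 rose and none fell (camera adjusted p = 2.33e-06, adjusted p = 0.357 with an estimated correlation). Of 14 NF-kB targets and chemokines 1 rose, the monocyte chemokine CCL2 by 1.62 at a mean of 132 CPM, while 2 rose and 1 fell when adjusted over the list alone (camera up, adjusted p = 0.0218, adjusted p = 0.265 with an estimated correlation). Without that library 6 rose and 1 fell (camera adjusted p = 0.046, adjusted p = 0.357 with an estimated correlation). Of 17 hypoxia targets 2 rose and none fell, the carbonic anhydrase CA12 by 2.57 and the lysyl oxidase LOX by 2.43, and 5 rose and 1 fell when adjusted over the list alone (camera up, adjusted p = 0.0136, adjusted p = 0.288 with an estimated correlation). Of 20 apoptosis regulators 2 rose, the pro-apoptotic BMF by 1.64 and the anti-apoptotic BCL2L1 by 1.31, and 2 when adjusted over the list alone (camera up, adjusted p = 0.0304, adjusted p = 0.265 with an estimated correlation).

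The remaining lists called up in PANC-1 held few or no genes past edgeR's test over all genes. COL1A1 was the 1 of 14 TGF-beta targets that rose, 3 when adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.265 with an estimated correlation). Of 9 Wnt targets none passed and 3 rose when adjusted over the list alone, with TCF7 at 0.69 ± 0.199 (SE) and DKK1 at 0.22 ± 0.235 (SE; camera adjusted p = 0.000376, adjusted p = 0.181 with an estimated correlation). None of 19 ATF4 targets passed, also when adjusted over the list alone, with SLC7A5 at -0.03 and MTHFD2 at 0.09 (camera adjusted p = 0.0188, adjusted p = 0.432 with an estimated correlation). None of 14 YAP targets passed, also when adjusted over the list alone, with ASAP1 at 0.58 and TEAD1 at 0.57 ± 1.386 (SE; camera adjusted p = 0.0304, adjusted p = 0.265 with an estimated correlation). None of 4 squamous differentiation genes passed, 1 when adjusted over the list alone, with the desmocollin DSC3 at 2.83 ± 1.197 and filaggrin, FLG, at -0.10 ± 0.797 (SE; camera adjusted p = 0.0421, adjusted p = 0.486 with an estimated correlation). Without empty vector replicate 2, camera still called the Wnt (adjusted p = 0.0268) and ATF4 (adjusted p = 8e-05) lists up, each with an adjusted p of at least 0.357 with an estimated correlation, and not the hypoxia, apoptosis, TGF-beta, YAP and squamous lists. Of these, 7 hypoxia targets then rose and 2 fell, 6 and 2 apoptosis regulators, 6 and 1 TGF-beta targets, 5 and 1 YAP targets and 2 and 1 squamous genes. Their mean log2 fold changes were 0.328, 0.284, 0.391, 0.318 and 0.845 without that library and 0.391, 0.307, 0.418, 0.302 and 1.197 with it, so the lost calls do not show that these changes came from that library.

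Lists of ribosomal, mitochondrial and cell cycle genes were called down in PANC-1 with no member past edgeR's test, over all genes or when adjusted over the list alone. Empty vector replicate 2, with its higher mitochondrial DNA share (18.8%), is 1 of the 3 empty vector libraries in these tests. The 30 ribosomal protein genes had a median log2 fold change of -0.53, with RPL4 at -0.37 and RPS6 at -0.47 (camera adjusted p = 9.72e-09, adjusted p = 0.487 with an estimated correlation). The 27 DNA replication genes had a median of -0.29, with MCM7 at -0.29 and RFC4 at -0.23 (camera adjusted p = 0.00303, adjusted p = 0.181 with an estimated correlation), and the 27 mitosis genes a median of -0.12, with MKI67 at -0.53 and CENPE at 0.24 (camera adjusted p = 0.0395, adjusted p = 0.265 with an estimated correlation). The 33 complex I genes had a median of -0.32, with NDUFB5 at -0.12 and NDUFA5 at 0.20 (camera adjusted p = 0.00818, adjusted p = 0.612 with an estimated correlation). Complexes II to IV (22 genes, median -0.23, UQCRB -0.36, CYCS 0.06) had a camera adjusted p of 0.0395 (adjusted p = 0.612 with an estimated correlation). ATP synthase (15 genes, median -0.26, ATP5F1A -0.07, ATP5PB -0.24) had 0.031 (adjusted p = 0.587 with an estimated correlation) and the mitochondrial ribosome (27 genes, median -0.20, MRPL3 0.03, MRPL15 -0.19) had 0.0284 (adjusted p = 0.586 with an estimated correlation). Without that library, 15 of 30 ribosomal protein, 10 of 27 DNA replication and 10 of 27 mitosis genes fell, and 1 mitosis gene rose (camera adjusted p = 2.32e-05, 2.14e-05 and 0.00416, adjusted p = 0.458, 0.357 and 0.357 with an estimated correlation). Complex I then turned to a median of 0.03 (camera adjusted p = 0.733) and complexes II to IV to 0.08 (camera adjusted p = 0.527), while ATP synthase had 0.02 (camera adjusted p = 0.84) and the mitochondrial ribosome 0.01 with 3 members down (camera adjusted p = 0.443), so none of these 4 lists kept its call.

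The PANC-1 lists closest to the study's subject had no member past edgeR's test with all 6 libraries. In pyrimidine synthesis (16 genes, 0 when adjusted over the list alone), DHODH had a log2 fold change of -0.04 ± 0.193, CAD of -1.33 ± 0.639 and UMPS of -0.16 ± 0.114 (SE), and the abundant members NME2 and CMPK1 of -0.42 and 0.15 (camera adjusted p = 0.483). In pyrimidine salvage and breakdown (18 genes, 2 up when adjusted over the list alone), UPP1 had -0.02 and DCTD 0.07 (camera adjusted p = 0.393). In gemcitabine handling (19 genes, 0 when adjusted over the list alone), the nucleotidase NT5C2 had 0.39 and CMPK1 0.15 (camera adjusted p = 0.104). Limma's fry called the salvage and breakdown and the gemcitabine lists up (adjusted p = 0.0293 and 0.0413). In L3.6 it had called the salvage and breakdown list down. Without empty vector replicate 2, 3 of the 16 pyrimidine synthesis genes fell and none rose, 8 down and 1 up when adjusted over the list alone (camera adjusted p = 0.126). Among them were TYMS (-0.235) and NME1 (-0.148), named after their values were seen, while DHODH, CAD and UMPS had 0.06, -0.30 and -0.13, none of these past the test. Of the 18 salvage and breakdown genes 3 rose and none fell (camera adjusted p = 0.252), among them NT5E (0.695) and TK2 (0.354), and of the 19 genes of gemcitabine handling 4 rose and 1 fell (camera adjusted p = 0.153), with NT5C2 at 0.26 (edgeR adjusted p = 0.000985). The basal-like signature (11 genes, 2 up and 2 down when adjusted over the list alone) had the glucose transporter SLC2A1 at 0.83 and the protease CTSV at 0.40 (camera adjusted p = 0.761). Without that library 3 rose, SLC2A1 by 1.04 (edgeR adjusted p = 2.96e-05), CTSV by 0.39 and DHRS9 by 1.07, and 2 fell, ANXA8 (-0.75) and FGFBP1 (-1.59), the same numbers when adjusted over the list alone (camera adjusted p = 0.437). DHRS9, ANXA8 and FGFBP1 are named after their values were seen. The classical signature (5 genes, 0 when adjusted over the list alone) had AGR2 at -0.46 and CDH17 at 0.28 (camera adjusted p = 0.529), and without that library 1 fell, AGR2 (-0.25). The 13 genes of mitochondrial DNA (0 when adjusted over the list alone) had MT-ND4 at -0.28 and MT-CO1 at -0.23 (camera adjusted p = 0.0548), and 0.09 and 0.04 without that library, where 3 of the 13 rose and 2 fell (camera adjusted p = 0.46).

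Among markers of other cell types, 2 collagen genes changed in PANC-1. Of 9 fibroblast markers 1 rose, COL1A1, and 1 fell, the fibrillar collagen COL3A1 (-2.84 at a mean of 1.67 CPM), with 1 up and 2 down when adjusted over the list alone (camera adjusted p = 0.761). Of 5 immune and 6 endothelial markers none passed edgeR's test or when adjusted over the list alone (camera adjusted p = 0.695 and 0.912), with CD68 at -0.13, CD14 at 0.88, PECAM1 at -0.45 and EMCN at 0.30. The immune list's median was -0.13 and its mean 0.26, and the endothelial median was 0.01 and its mean -0.13. The 1 acinar or islet marker with enough counts, CEL, did not pass.

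**Figure D3:**
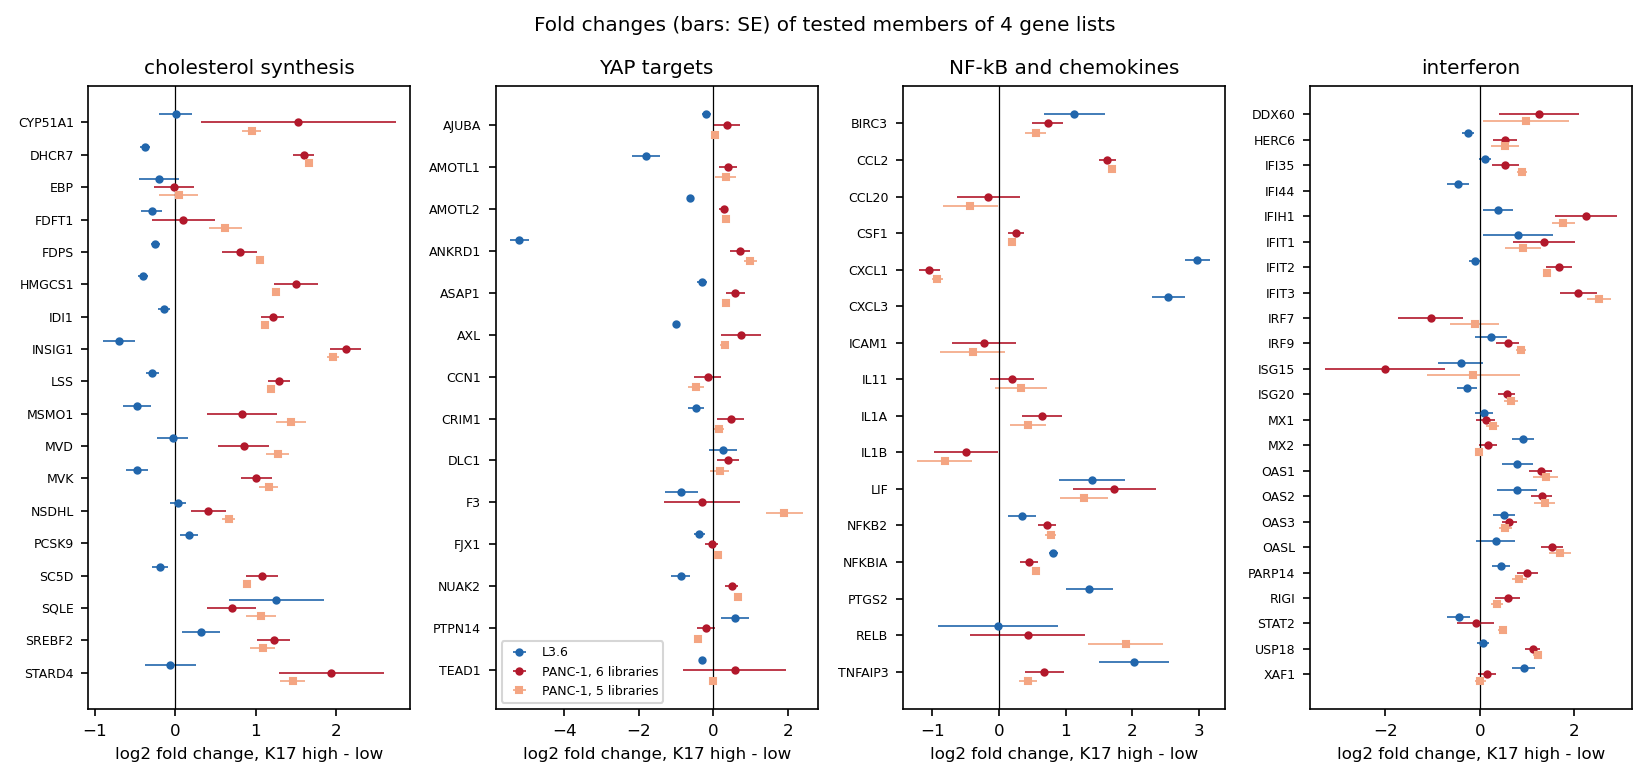
Log2 fold changes (K17 high minus low; bars are standard errors) of tested members of 4 gene lists, leaving out those not reported here, for L3.6 (blue), PANC-1 with all 6 libraries (dark red) and PANC-1 without empty vector replicate 2 (orange squares, 5 libraries). In cholesterol synthesis and uptake, 17 of 19 PANC-1 members rose without that library, and 4 of 20 L3.6 members fell.

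The K17 effects of the 2 human lines differed for part of the genes. K17 was introduced in PANC-1 and knocked out in L3.6, so the line cannot be told apart from the way K17 was changed. Within each line, K17 also cannot be told apart from other differences between its groups. CXCR4 fell with K17 in L3.6 (-2.11) and rose in PANC-1 (2.07, from 0.295 ± 0.0395 to 1.25 ± 0.0484 CPM), a difference of 4.15 ± 0.256 (SE; edgeR interaction adjusted p = 1.62e-05). ANKRD1 had a difference of 5.84 ± 0.444 (SE; edgeR adjusted p = 7.33e-05), with -5.20 in L3.6 and 0.70 in PANC-1. CXCL1 had a difference of -4.08 ± 0.264 (SE; edgeR adjusted p = 2.47e-05) and INSIG1 of 2.79 ± 0.241 (SE; edgeR adjusted p = 0.000165). In all, 270 of 17583 genes passed edgeR's test of the difference, 220 with a higher effect in PANC-1 and 50 with a lower one. Without PANC-1 empty vector replicate 2, 1819 passed, 1374 higher and 445 lower. Differences of 46 lists were tested after the data were seen, and camera called 12 up and 3 down in PANC-1 against L3.6. With an estimated correlation 5 passed, all up: cholesterol (camera adjusted p = 4e-14, adjusted p = 0.00102 with an estimated correlation), the mesenchymal and TGF-beta lists (both 0.0232 with an estimated correlation) and the integrin and YAP lists (both 0.0306). The NF-kB list was down (camera adjusted p = 0.0395, adjusted p = 0.274 with an estimated correlation). Without that library 14 were up and 3 down, and 0 passed with an estimated correlation (lowest 0.0555, cholesterol).

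Few genes were called in the same K17 direction in both human lines. Among 13262 genes tested in both, 7 rose in both where independent lists would share 2.57 (Fisher's exact test over genes, two-sided, p = 0.0143), and 1 fell in both where 0.37 would be shared (p = 0.317). The 7 that rose were COL1A1 (0.41 in L3.6 and 2.31 in PANC-1), SDR16C5, PLEKHA7, SH3RF3, ZNF620, SRPX2 and LPIN1, and the desmoplakin gene DSP fell (-0.74 and -2.25). These 8 genes are named after their values were seen. No gene was shared in 1 direction with the replicate block, or without L3.6 wild-type replicate 2, PANC-1 empty vector replicate 1 or 3, or any single PANC-1 K17 library, and 1 gene was shared without L3.6 knockout replicate 2 or 3. Opposite calls were made for 9 genes where 4.87 would be shared, among them CXCR4 and DHCR7 (-0.38 in L3.6 and 1.60 in PANC-1). Fold changes of the lines had a Spearman correlation of 0.048 over genes, which are not independent replicates. Without PANC-1 empty vector replicate 2, 91 genes rose in both (58.4 for independent lists, Fisher's exact p = 1.19e-05), 120 fell in both (89.67, p = 0.000781) and 289 went opposite ways (155.3, not tested). The Spearman correlation was then -0.01. Calls in 1 direction and opposite calls both exceeded the numbers for independent lists, so the Fisher p-values do not show a shared K17 response.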

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

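Tests of GC content, transcripts, shared sequence, other cell lines and other splits of the samples were written before their results were seen, while the correction for GC content and length, the fit without AC010970.1, the place of wild-type replicate 1, the ratio for knockout libraries and the split with the PANC-1 direction reversed were chosen after the data were seen. The K17 effects of PANC-1 and L3.6 differed in 270 genes, by edgeR's test of the difference over 12 libraries. This test cannot separate the line from the way K17 was changed, or K17 from other differences between the groups of a line. Of the genes named here, the log2 effect was higher in PANC-1 for KRT17 (10.51, which depends on the prior count), ANKRD1 (5.84), EFEMP1 (4.20), CXCR4 (4.15), PDGFB (4.07), INSIG1 (2.79), WNT5A (2.74), BDNF (2.66), MANSC1 (2.37), MAST4 (2.36), MMP2 (2.22) and COL1A1 (1.85). It was lower in PANC-1 for CXCL3 (-4.23, with too few PANC-1 counts for a test in that line alone), HEATR4 (-4.09), CXCL1 (-4.08), ADGRF1 (-2.78), TNFAIP2 (-2.34), IGFBP3 (-2.25), ERBB2 (-1.14) and C3 (-1.12). Each of these 20 genes also passed the test without PANC-1 empty vector replicate 2. Of 41 splits of the samples, the real groups with the PANC-1 direction reversed gave 315 genes, the highest other, and the rest at most 41. Those splits also remove the K17 effects of a line, so they do not show whether the effects of the lines differ by chance, and the count is no larger than with the direction reversed.

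PANC-1 empty vector replicate 2 differed from the other empty vector libraries by at least 4-fold in 684 of 8838 genes at 5 CPM or more, where replicates 1 and 3 differed so in 6. GC content and transcript length explained 18.1% of the variance of its log2 ratios, against 0.1% between replicates 1 and 3. That is too little for a whole cause, but part of the deviation of replicate 2 followed GC content and length. Correcting for GC content and length gave 419 genes in place of 105. Rows holding 1 transcript of a gene would put the jumps in genes with many transcripts, but their share there was 0.572 times that of genes with 1 transcript (5.83% against 10.2%). RNA of L3.6 in that library was argued against by a median of 0.0627% of the L3.6 level over 24 genes. The design names no biological difference within the group, so no biological explanation was tested, and damaged RNA or a mislabelled sample may still apply. A swap with a PANC-1 K17 library is argued against by its KRT17 count of 0, where those libraries had 8597 to 9884.

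L3.6 wild-type replicate 1 lay nearer to the knockout than wild-type replicates 2 and 3. Its lower share of AC010970.1 was argued against as the whole cause. On the first component, from 0 for the knockout mean to 1 for wild-type replicates 2 and 3, replicate 1 lay at 0.54 with that row and 0.491 without it with no scaling factors (0.527 and 0.522 with TMM), and 1381 genes passed without the row (1335 with it). Genes called without replicate 1 kept a median of 0.552 times their effect in it, where a knockout library left out of the calls gave -0.0465 to 0.21. Knockout cells mixed into it were predicted to give KRT17 the same ratio in CPM as the median of the called genes. The KRT17 ratio of 0.858 lay above that median of 0.559 but inside the quartiles (0.25 to 0.864). This 1 gene in 1 library did not decide the question. The called genes were also picked by their effects in replicates 2 and 3, which can lower their ratios. The ratios of KRT17 and of these genes need therefore not be equal under mixing. A culture difference may remain, and was not tested.

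Abundant ribosomal protein genes ranged from 8.45 to 2894 CPM, with 11 of 30 under 100. Splitting of reads over a gene's transcripts predicted lower counts in genes with more annotated transcripts, and the rho over genes was 0.03. Each of the 30 genes has at least 5 annotated transcripts (27 for RPLP0), so this does not rule out rows that hold 1 transcript. Reads shared with pseudogenes or paralogs may contribute and stay open, with a rho of -0.32 with the percent of shared 31-base words (permutation p = 0.0876, two-sided, over 30 genes, which are not independent).

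Splits of 3 against 3 libraries (10 in all) are too few for a share under 0.05. The real split gave 4990 genes in KPC (highest other 1), 1335 in L3.6 (highest other 0) and 105 in PANC-1 (highest other 0), and in each it was 1 of the 10 splits with as many. For gene lists the real split gave 8 in L3.6 (highest other 5) and 18 in PANC-1 (highest other 8).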

How the results depend on the processing

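Quality weights, the GC and length correction, genes with 1 transcript and the fit without AC010970.1 were chosen after the data were seen. The KPC counts (4990, and 633 at 2-fold) stayed within 1.5 times under every alternative run, from 4052 to 5611 and 586 to 818 with 1 library left out. The L3.6 KRT17 effect kept its direction and its call in every alternative run, from 2.94 to 3.03 with 1 library left out. In L3.6 the counts (1335, 245) became 665 and 162 with the replicate block, 204 and 120 in 1 fit of 4 groups and 2254 and 480 with quality weights, and ranged from 574 to 2493 and from 148 to 563 with 1 library left out. In PANC-1 the counts (105, 100) became 511 and 356 with DESeq2, 363 and 234 in 1 fit of 4 groups, 419 and 240 with the GC and length correction, 3030 and 567 with quality weights, and 0 and 0 among the 2193 genes with 1 transcript by edgeR (160 at an unadjusted p under 0.05). With the replicate block edgeR called 0 and 0 (1262 at an unadjusted p under 0.05), and with 1 library left out the counts ranged from 0 to 3442 and from 0 to 494. PANC-1 KRT17 kept 13.65 with the replicate block but not its call (edgeR adjusted p = 0.262, range over its other alternatives 1e-35 to 0.127), and ranged from 13.13 to 16.22 with 1 library left out. The difference between lines (270) became 749 with DESeq2 and 70 with the replicate block, and ranged from 138 to 1819. Genes called in both lines in 1 direction (8) became 5 with no filter, 33 with DESeq2, 0 with the replicate block and 275 with quality weights, and ranged from 0 to 211 with 1 library left out. Of 100 splits the real 1 gave 8 and the highest other 0, but the other splits of L3.6 and those of PANC-1 each called 0 genes by edgeR, which fixes a shared count of 0, so these splits say nothing about chance. Lists called (8 in L3.6, 18 in PANC-1) became 0 and 0 with an estimated correlation, and ranged from 6 to 9 and from 10 to 18 with 1 library left out. In PANC-1 the direction of complex I (camera adjusted p = 0.733) and of complexes II to IV (0.527) turned up without empty vector replicate 2, and with 1 library left out their adjusted p ranged from 0.000208 to 0.733 and from 0.00947 to 0.527. Fewer samples explain part of the counts with 1 library left out; otherwise the cause was not tested. Of the named genes, 23 of 62 called in L3.6 and 0 of 23 called in PANC-1 kept their call in every alternative run, and 0 changed sign while called. The replicate numbers do not pair the samples: 0 of 9 same-numbered pairs had correlated deviations over 0.1 (-0.213 to 0.086), and 3 correlated best with their own number. The pseudocount alternatives, meant for normalized values, were not run, and neither was the overlap of 3 lines; the KPC row of Krt17 was not determined. In the simulated PANC-1 design 1 of 100 2-fold changes was found, so changes of that size were mostly not detectable in that simulation. It spread the deviation of empty vector replicate 2 over all libraries, so the share found in the real design may differ.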

Other observations

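List tests with each PANC-1 library left out in turn were planned. The detailed account without empty vector replicate 2 was chosen after that library was seen to stand apart, and the genes named here after their values were seen. In the other 5 PANC-1 libraries, MYLK, the myosin light chain kinase, rose with K17 from 78.3 ± 0.363 to 320 ± 5.53 CPM (log2 fold change 2.03, edgeR adjusted p = 3.83e-07), and NCR3LG1, a ligand of a natural killer cell receptor, rose by 2.34. The glutamate receptor GRIK2 (-1.79) and the oxidoreductase ERO1B (-1.38) fell. Of 23 interferon-stimulated genes 13 rose, among them IFIT3 (2.52), IFIH1 (1.77) and OASL (1.70), and of 19 ATF4 targets 10 rose, among them NUPR1 (1.78), VLDLR (1.44) and GDF15 (1.11). Of 21 ribosome biogenesis genes 9 fell and none rose, 10 when adjusted over the list alone, among them POLR1A (-0.45) and NCL (-0.19; camera adjusted p = 0.000804, adjusted p = 0.357 with an estimated correlation). Of 13 antigen presentation genes 6 rose and none fell, 7 when adjusted over the list alone, among them ERAP1 (0.55), TAP1 (0.48) and B2M (0.19; camera adjusted p = 0.046, adjusted p = 0.357 with an estimated correlation). Of 23 DNA damage repair genes 7 fell and none rose, 10 down and 1 up when adjusted over the list alone (camera adjusted p = 0.0169, adjusted p = 0.357 with an estimated correlation), and of 20 genes of autophagy and the lysosome 7 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.046, adjusted p = 0.458 with an estimated correlation).

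Genes called in both human lines without that library included the stress cytokine GDF15, which rose by 1.35 in L3.6 and 1.11 in PANC-1, the NF-kB inhibitor NFKBIA (0.81 and 0.56) and GPRC5A (0.67 and 0.61), while the plexin PLXND1 (-0.85 and -0.43) and the replication protein RPA1 (-0.69 and -0.29) fell. In L3.6, 3 squamous differentiation genes had enough counts, too few for a list test: TP63, the squamous transcription factor, fell by 0.48 and DSC3 by 0.40, while DSC2 (0.30 ± 0.241, SE) did not pass edgeR's test. With all 6 PANC-1 libraries, further genes with opposite calls were DKK3, a secreted Wnt antagonist (-1.71 in L3.6, 0.96 in PANC-1), the vitamin D receptor VDR (-0.28 and 2.08) and the protease inhibitor TIMP2 (-0.66 and 1.63).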
